A study of Drosophila melanogaster with 6 samples.

How the data were processed

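Gene expression was measured on Affymetrix Drosophila Genome 1 arrays in cells sorted by flow cytometry from Drosophila embryos that carried the TinD-GFP reporter, which per the labels marks cardiac mesoderm. The embryos were between late stage 11 and early stage 12. There were 3 arrays of GFP-positive and 3 arrays of GFP-negative cells, grouped by their titles. The labels do not say that the replicates came from separate embryo collections or sorts. P-values for single genes and quality values therefore measure only the spread between these samples, which may be technical.

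The authors deposited 1 log2 value per probe set and array. Per the submitters' processing notes the affy package was used, with no version or role. The background correction, the scaling between arrays and the summary method are not given in the sources used here. The base of the logarithm is not stated either. It was read as 2 because 2 to the power of the value stays below the 65535 of a 16-bit scanner on every array, with a highest value of 12.9, while powers of e or 10 exceed it. The array medians of the deposited log2 values lay between 3.71 and 3.73, and the upper quartiles between 5.66 and 5.69, while the lowest values ranged from -3.28 to -2.30. No further scaling was applied. If the arrays were scaled to a like level before deposit, a change shared by most genes cannot be seen. Where the mean of a group lies at or below the background level given next, a fold is given only as a lower bound, the brighter group's mean against that level. Precision is limited by the number of arrays.

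Of 14010 probe sets, 44 controls were left out and 13966 were tested. The highest mean of the 23 control probe sets for other organisms, 2.44, served as the background level. On single arrays the highest of these controls lay at 2.58 to 3.55, so fold bounds from means near 2.44 are not firm. Genes were named through a table of the platform's annotation. It gives 1 gene for 12443 probe sets, several for 327 and none for 1196, and no gene was named from a probe set with several. Of the probe sets with 1 gene, 12394 matched the reference gene table (assembly Release 6 of the fly genome) by Entrez identifier, and no symbol changed. For lists and named genes, 1 probe set per gene was used, the one with the highest mean over all arrays, which left 10844 genes. Several genes fixed in advance, among them members of the lists, and a planned check on the reporter's own gene are not analysed here.

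The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjustment over all tested probe sets, threshold 0.05), as GFP-positive minus GFP-negative. The design set before the data were examined used a single prior variance for all probe sets and no block. Gene lists, 32 in all, were written before the data were examined. They cover cardiac, pan-mesodermal, somatic muscle, sarcomere, visceral and fat body or gonadal mesoderm genes, hemocytes, basement membrane, epidermis, segment polarity, neuroblasts, neurons, glia, midgut, trachea, salivary gland, germline, Forkhead factors, cell division, DNA replication, asymmetric division, Wnt, FGF/EGF/Ras, BMP, Notch, Hox and Hedgehog genes, heat shock and stress, ribosomal proteins, mitochondrial respiration, glycolysis and yolk or fat body products. The 31 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. The Hox list had fewer measured genes and was not tested. At the preset correlation camera takes its degrees of freedom from the genes, so its p-value measures the spread across genes and not between arrays. Camera was run again with an estimated correlation, where it takes them from the arrays, which are far fewer. Fry served as a further alternative.

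The genes to be named were set by a rule before the data were examined. It takes a few genes whatever their values, the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold without overlap of the groups, and per list up to 4 members past the threshold, or up to 2 given as values where fewer than 2 pass. Not all of the latter are printed below. Because the fit with a single prior variance called no probe set, the rule was applied to limma with a prior variance that depends on the mean level (trend and robust options). That fit was listed beforehand as an alternative, but its use for naming genes was decided after the first fit gave no call. Unless stated otherwise, gene-level adjusted p-values, standard errors (SE) and the words rose and fell refer to it. Lists were called with camera and the single prior variance, as set beforehand.

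The other alternatives listed beforehand were a block on replicate number, quantile normalization, median centring, leaving out each array in turn, array weights, leaving out the dimmest 40% of probe sets, adding a pseudocount of 32 on the linear scale, a 2-fold limit, non-overlap with a 2-fold limit, the mean of all probe sets of a gene, an estimated correlation and fry. Another 4 kinds of alternative were added after the data were seen. They are an adjustment for gene span (per array, a loess fit on the log2 annotated span and the mean level was removed), the same genes without that adjustment, every setting repeated with the level-dependent prior variance, and the hemocyte list without its basement membrane members. Exact permutation tests compared single quality values, and 3 arrays against 3 cannot give an exact p below 0.1.

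Both fits were tested on simulated arrays with the real mean levels and level-dependent spread, over 13966 probe sets with 200 changed, all 200 at mean levels above 4. Recovery of dimmer probe sets, whose spread is larger, was not simulated. With the level-dependent prior variance, 22% of changes of 0.5 and 72% of changes of 1 on the log2 scale were recovered, with 7 false calls among 101. With a single prior variance 0% of either were recovered. Spreads were drawn from the level-dependent fit's own prior, so its higher recovery does not show that it suits the real arrays better. A simulated list of 16 genes raised by 0.6 was called, and 0 of 29 lists without a shared gene were. In these simulations the values were drawn independently, so false calls among genes that move together were not tested. A simulated trend with gene span (Spearman's rho 0.650) fell to 0.0227 after the span adjustment. Plots were drawn with matplotlib.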

Results

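Embryos of a Drosophila line in which the TinD-GFP reporter labels cardiac mesoderm were dissociated at late stage 11 to early stage 12, and RNA of sorted GFP-positive and GFP-negative cells was measured on 3 arrays each. The comparison asks which genes differ in level between the labelled cells and the remaining cells of the embryo. The series concerns Forkhead transcription factors and the division of cardiac progenitor cells, so those gene groups were examined as well. Pearson's r between arrays over all tested probe sets lay between 0.917 and 0.945, with a mean of 0.932 within groups and 0.930 between groups. The 6 arrays differed about as much within a group as between groups by this measure. Over probe sets with a mean above the background level, mean r was 0.945 within and 0.937 between groups.

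In GFP-positive cells, genes of somatic muscle formation and of the basement membrane were higher, and genes of DNA replication were lower. At camera's estimated correlation the somatic muscle and DNA replication lists passed and the basement membrane list did not (adjusted p = 0.068). Among single genes, RyR, the ryanodine receptor calcium channel, rose by 2.04 ± 0.14 (log2, SE, n = 3 per group), CRMP, a collapsin response mediator protein, by 1.40 ± 0.10, and sls, the titin-like sallimus, by 1.15 ± 0.15. The adjusted p-values were 4.1e-04, 4.1e-04 and 0.0065. The mucin gene Muc12Ea had the largest rise of the called genes, 3.02 ± 0.56 (adjusted p = 0.030). Its GFP-negative mean of 2.77 ± 1.22 (SD) lay near the background level of 2.44, and across settings its rise went down to 1.14. It stayed past the threshold in 2 of 6 fits without 1 array. The DNA polymerase epsilon subunit gene PolE2 fell by 1.73 ± 0.35, and RPA2, a subunit of the single-strand DNA binding complex, fell by 0.71 ± 0.09, with adjusted p-values of 0.040 and 0.0052. The GFP-positive mean of PolE2, 2.73, also lay near the background level, and across settings its difference shrank to as little as -0.48.

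Further genes that rose were CG31038 (1.28 ± 0.25), CG11825 (1.18 ± 0.06), gol, which encodes the RING finger protein goliath (1.16 ± 0.24), Duox, the dual oxidase (1.14 ± 0.24), and the glue protein gene Sgs7 (1.32 ± 0.27), each as log2 difference with SE. CG13247 and Jhbp12 also passed as higher, but their GFP-negative means lay below the background level. Their GFP-positive means of 2.48 and 2.57 lay just above it, so against that level the rise was at least 1.02-fold and 1.09-fold. Both lay below the highest control of each single array, 2.58 to 3.55, so these bounds are not firm. Genes that fell were grsm (-1.43 ± 0.30), the exosome subunit gene Rrp46 (-0.79 ± 0.13), Torsin (-0.74 ± 0.12), link (-0.73 ± 0.07), the deubiquitinase gene Yod1 (-0.72 ± 0.13) and Naa40 (-0.70 ± 0.14). Mms19, CG4325 and CG9411 had GFP-positive means below the background level, with 4.47, 3.11 and 2.57 in GFP-negative cells. Against that level they were at least 4.07-fold, 1.59-fold and 1.09-fold lower. For CG4325 and CG9411 the bounds are not firm, as a control reached 3.55 on GFP-negative replicate 1.

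With the single prior variance set in advance, limma called 0 of 13966 probe sets, with a smallest adjusted p of 0.112. At an unadjusted p under 0.05 it gave 1482 probe sets, 813 higher and 669 lower, where chance gives 698.3. With the level-dependent prior variance, 340 probe sets passed, 215 higher and 125 lower, and they named 163 genes that rose and 105 that fell. The groups did not overlap in any of the 340. Over all probe sets 2745 showed no overlap, and chance gives 10%. The median log2 difference of the called probe sets was 0.58 for those higher and -0.43 for those lower, and 36 changed at least 2-fold, 29 of them higher. The median within-group SD was 0.87 at mean levels of 0 to 2 and 0.077 above 8. Leaving out GFP-positive replicate 1, 2 or 3 left 139, 102 or 154 calls, and leaving out GFP-negative replicate 1, 2 or 3 left 189, 180 or 120. Of 57 named genes that were called, 12 stayed past the threshold without any 1 array, namely lmd, sls, so, borr, RyR, CRMP, CG11825, link, RPA2, PCNA, Mcm2 and ND-B17.2, and the remaining genes lost the call without at least 1 array. The calls of vkg, par-1, gol, mib2, bap, tud, numb, S, Tom, puc, CG13247, Jhbp12, CG4325 and CG9411 were lost whichever array was left out. With a block on replicate number 11 of the 57 no longer passed, namely PolE2 (adjusted p = 0.055), vkg (0.070), Vrp1 (0.053), gol (0.069), Sgs7 (0.071), grsm (0.054), puc (0.052), par-1 (0.079), CG13247 (0.066), Jhbp12 (0.060) and CG9411 (0.070). After an adjustment for gene span, chosen after seeing the data, 31 of the named genes no longer passed. Without the adjustment all 31 passed among the same genes. In 25 of the 31 the log2 difference shrank by at least 10%. Con went from 0.97 ± 0.17 to 0.72 ± 0.17 (SE), rols from 0.91 to 0.68, LanB1 from 0.70 to 0.55, if from 0.78 to 0.57, vkg from 1.11 to 0.98, nkd from 0.72 to 0.46, aurB from -0.42 to -0.29, Mcm5 from -0.50 to -0.44 and puc from 0.48 to 0.30. The differences of numb (0.35 to 0.09), S (0.34 to 0.09) and kuz (0.49 to 0.17) shrank further. The other 6 changed by less than 10%, among them PolE2 (-1.73 ± 0.35 to -1.69 ± 0.35, adjusted p = 0.063), Sgs7 (1.32 ± 0.27 to 1.31 ± 0.28, adjusted p = 0.067) and gol (1.16 ± 0.24 to 1.06 ± 0.24, adjusted p = 0.081), so their lost calls do not show an effect of span on them.

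Signal also moved with gene span. Over 5170 genes with a mean level above 4, the median log2 difference was -0.18 in the decile with the shortest annotated spans and 0.24 in the decile with the longest, and Spearman's rho across genes was 0.43. Over all 10803 genes with a known span rho was 0.17.

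**Figure D1:**
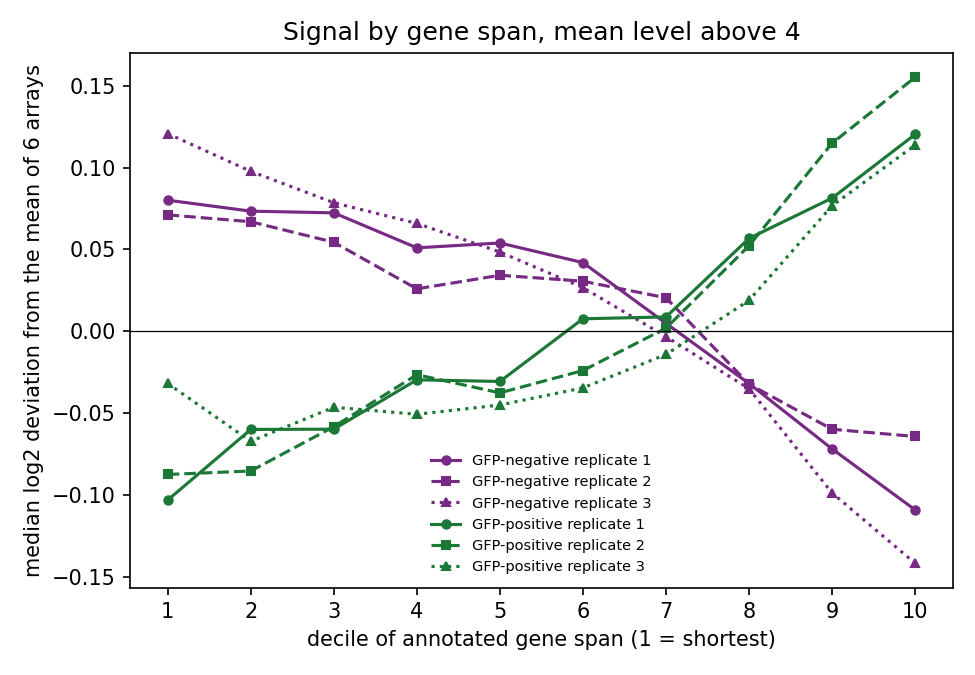
Median log2 deviation from the mean of all 6 arrays by decile of annotated gene span, for genes with a mean level above 4; each line is 1 array, green for GFP-positive and purple for GFP-negative cells. In the decile of the longest genes all 3 GFP-positive arrays lie above 0 and all 3 GFP-negative arrays below it.

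The somatic muscle list holds genes of founder cells, fusion-competent myoblasts and myoblast fusion. Its median log2 difference was 0.62 over 16 measured genes (camera adjusted p = 7.0e-09, and adjusted p = 0.048 with an estimated correlation), and 15 of the 16 were higher. By the level-dependent fit 6 rose, none fell and 10 did not pass. Adjusted over the list alone, 7 were higher with the single and 8 with the level-dependent prior variance. lmd, the zinc finger factor of fusion-competent myoblasts, had a log2 signal of 8.37 ± 0.12 in GFP-positive and 7.32 ± 0.09 in GFP-negative cells (SD, n = 3 each), a rise of 1.05 ± 0.08 (SE, adjusted p = 6.7e-04). The muscle adhesion gene Con rose by 0.97 ± 0.17, the fusion gene blow by 0.95 ± 0.13 and the founder cell adaptor gene rols by 0.91 ± 0.15.

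The sarcomere list had a median of 0.38 over 15 measured genes (camera adjusted p = 0.045, and adjusted p = 0.167 with an estimated correlation), of which 6 had a mean above background, and sls was the single member called. The member with the largest difference, up, ran the other way and did not pass (adjusted p = 0.470). Its means were 1.11 in GFP-positive and 2.61 in GFP-negative cells. The other probe set of up lay at 2.49 and 0.31, so near the background level of 2.44 no direction is shown. The list's camera adjusted p was 0.107 and 0.177 without GFP-positive replicates 2 and 3, and 0.123 and 0.124 without GFP-negative replicates 1 and 2, with medians of 0.33, 0.20, 0.26 and 0.16. Without GFP-positive replicate 1 the median was 0.58. The adjusted p was 0.101 after the span adjustment, 0.066 with a block on replicate number and 0.0503 with array weights (median 0.25). The median was 0.23 without dim probe sets and 0.034 with the pseudocount. With the single prior variance 1 sarcomere gene was higher adjusted over the list alone, and 2 were with the level-dependent one.

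**Figure D2:**
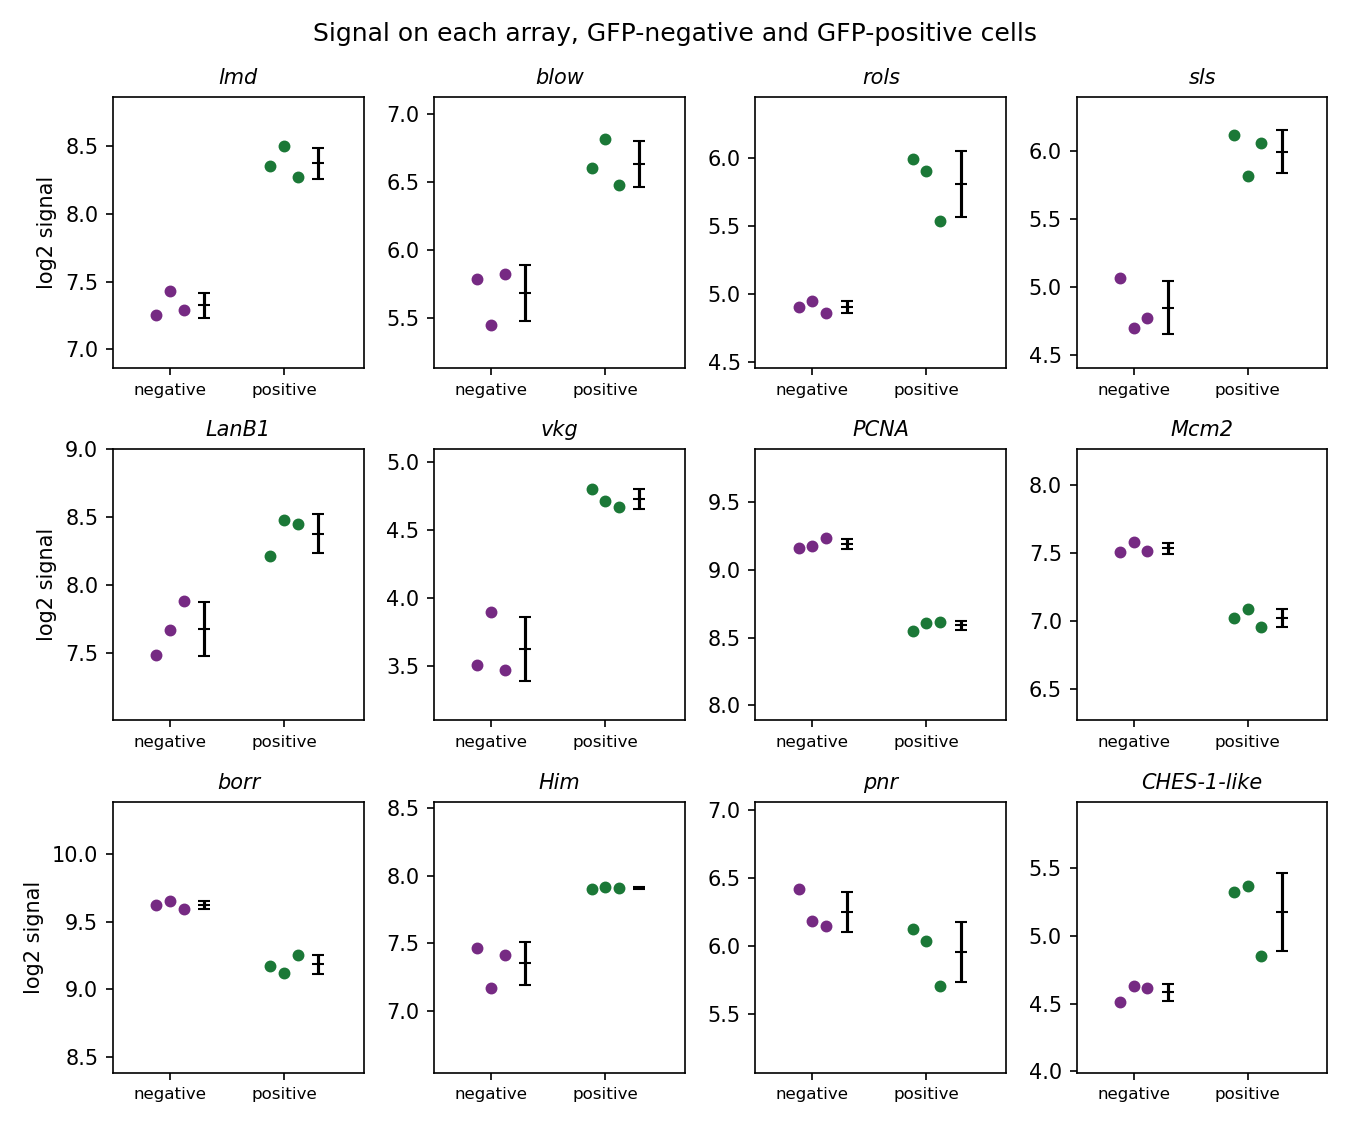
Log2 signal of 12 genes on each array, with GFP-negative cells in purple on the left and GFP-positive cells in green on the right of each panel; points are arrays, and the black mark and bars beside them are the mean and SD of 3 arrays. Each panel spans the same height on the log2 scale; lmd lies at 8.37 ± 0.12 in GFP-positive and 7.32 ± 0.09 in GFP-negative cells, and PCNA at 8.59 ± 0.04 and 9.19 ± 0.04.

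Basement membrane genes had a median log2 difference of 0.65 over 12 measured genes (camera adjusted p = 6.8e-09, and adjusted p = 0.068 with an estimated correlation), with 11 higher. By the level-dependent fit 6 rose and 6 did not pass. With p-values adjusted over the list alone, 8 were higher with the single and 10 with the level-dependent prior variance. The collagen IV gene vkg rose by 1.11 ± 0.23, the papilin gene Ppn by 0.85 ± 0.12, the nidogen gene Ndg by 0.72 ± 0.12 and the laminin gene LanB1 by 0.70 ± 0.11. Hemocytes, the blood cells of the embryo, also make much of this matrix, and the hemocyte list shared 5 members with the basement membrane list. Its median was 0.37 over 19 genes (camera adjusted p = 9.8e-05, and adjusted p = 0.086 with an estimated correlation), and 2 members rose, vkg and Ppn, which are both basement membrane genes. The median was 0.24 after the span adjustment, 0.23 with the mean of all probe sets and 0.22 with the pseudocount. Without the 5 shared members its median was 0.20 over 14 genes (camera adjusted p = 0.048, still past the threshold), an alternative chosen after seeing the data.

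The pan-mesoderm list had a median of 0.31 over 7 genes (camera adjusted p = 0.0011, and adjusted p = 0.104 with an estimated correlation). The integrin alpha subunit gene if rose by 0.78 ± 0.13 and Him, a muscle differentiation inhibitor, by 0.56 ± 0.08. The mesodermal factor twi differed by 0.28 ± 0.11 (adjusted p = 0.303), which did not pass, by 0.17 without GFP-positive replicate 3 and by 0.02 after the span adjustment. The visceral mesoderm list had a median of 0.41 over 10 genes, all higher (camera adjusted p = 9.8e-05, and adjusted p = 0.112 with an estimated correlation), and 3 rose: Vrp1, a WASP-interacting protein gene of myoblast fusion, by 1.01 ± 0.19, mib2 by 0.47 ± 0.08 and the visceral mesoderm homeobox gene bap by 0.42 ± 0.08. The fat body and gonadal mesoderm list had a median of 0.24 over 8 genes (camera adjusted p = 0.092), and so, a homeobox gene, rose by 0.91 ± 0.11. The fat body and gonadal list's camera adjusted p was 0.028 without GFP-positive replicate 3 (median 0.32) and 0.224 without GFP-positive replicate 1 (median 0.15), and 0.60 after the span adjustment (median 0.05). Adjusted over the list alone with the single prior variance, 3 pan-mesoderm, 2 visceral, 1 fat body or gonadal and 2 hemocyte genes were higher. With the level-dependent prior variance these counts were 4, 4, 2 and 10, and 1 fat body or gonadal gene was lower.

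Cardiac and dorsal mesoderm genes as a list did not pass the test. The median was 0.06 over 15 measured genes, 9 higher and 6 lower (camera adjusted p = 0.557). It was -0.086 without GFP-negative replicate 3, 0.36 without GFP-negative replicate 1, and 0.20 and 0.03 without GFP-positive replicates 1 and 2, and the list passed in none of these. The single member called was Him. The GATA factor gene pnr had a log2 signal of 5.96 ± 0.22 in GFP-positive and 6.25 ± 0.15 in GFP-negative cells (SD, n = 3 each), a difference of -0.29 ± 0.13 (SE, adjusted p = 0.354), which was -0.17 without GFP-positive replicate 3 and -0.47 after the span adjustment. The heart factor gene Hand had a log2 signal of 2.49 ± 1.09 in GFP-positive and 1.10 ± 1.57 in GFP-negative cells (SD, n = 3 each), the latter below the background level, and did not pass (adjusted p = 0.560). For lbe both means lay below that level. Adjusted over the list alone, 0 members passed with the single prior variance, and 2 higher and 2 lower with the level-dependent one.

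DNA replication genes had a median log2 difference of -0.38 over 23 genes, 19 of them lower (camera adjusted p = 7.7e-08, and adjusted p = 0.048 with an estimated correlation). By the level-dependent fit 6 fell and 17 did not pass. Adjusted over the list alone, 5 were lower with the single prior variance, and 14 lower and 1 higher with the level-dependent one. The sliding clamp gene PCNA fell by 0.60 ± 0.05 (adjusted p = 8.8e-04), RnrL, the large subunit of ribonucleotide reductase, by 0.67 ± 0.11, and the helicase genes Mcm2 and Mcm5 by 0.51 ± 0.07 and 0.50 ± 0.10. The cell division list, of mitotic regulators, had a median of -0.20 over 25 genes, 21 of them lower (camera adjusted p = 0.0030, and adjusted p = 0.104 with an estimated correlation). The median was -0.13 without GFP-negative replicate 1 and -0.13 after the span adjustment. There borr and aurB, both of the chromosomal passenger complex, fell by 0.44 ± 0.05 and 0.42 ± 0.07, and 23 genes did not pass. In these 25 genes, 0 passed adjusted over the list alone with the single prior variance and 2 were lower with the level-dependent one.

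Forkhead factor genes had a median of 0.25 over 16 genes and did not pass (camera adjusted p = 0.164), with 0 members called and 0 adjusted over the list alone in either fit. Without GFP-positive replicate 1 the list's adjusted p was 0.0497 (median 0.30), and without GFP-positive replicate 3 it was 0.553 (median 0.08). The Forkhead genes CHES-1-like and jumu differed by 0.59 ± 0.18 (adjusted p = 0.148) and 0.12 ± 0.07 (adjusted p = 0.519), the latter 0.07 without GFP-negative replicate 1 and -0.05 after the span adjustment. For foxo both means lay below the background level.

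**Figure D3:**
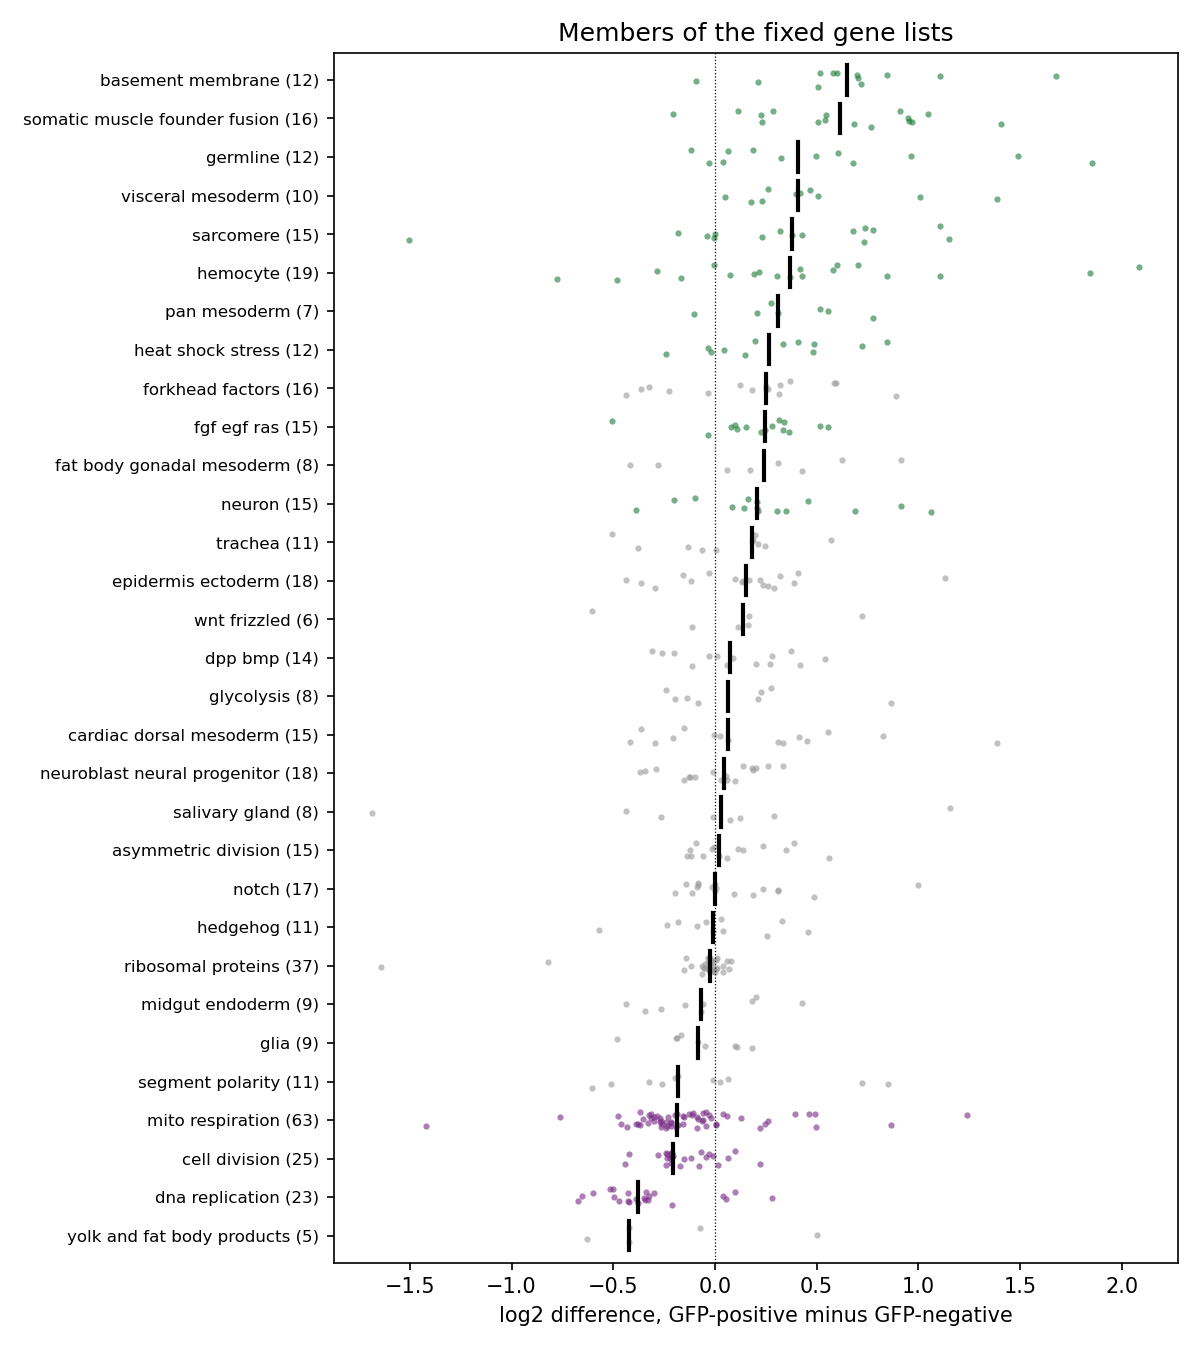
Log2 difference (GFP-positive minus GFP-negative, mean of 3 arrays each) of the members of each tested gene list, with the number of measured genes in brackets; each point is a gene and the black bar is the list's median. Lists past camera's adjusted threshold are green where higher and purple where lower, others grey; the basement membrane and somatic muscle medians lie at 0.65 and 0.62 and the DNA replication median at -0.38.

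Lists of markers of other cell types had medians of 0.04 for neuroblasts, -0.08 for glia, 0.18 for trachea, 0.15 for epidermis, -0.18 for segment polarity genes, -0.07 for midgut and 0.03 for salivary gland, none past camera's threshold. Without GFP-positive replicate 3 or GFP-negative replicate 1 or 2 the segment polarity median was -0.10, -0.09 or -0.06. The midgut median was -0.04 without GFP-positive replicate 3 or GFP-negative replicate 2, and -0.16 without GFP-negative replicate 3. The epidermis list passed with the level-dependent prior variance (adjusted p = 0.016), the pseudocount (0.039) and the mean of all probe sets (0.049). For the salivary gland list the mean (-0.09) and the test ran the opposite way to the median. The neuron list had a median of 0.21 over 15 genes (camera adjusted p = 0.040, and adjusted p = 0.167 with an estimated correlation) with 0 members called. It did not pass without GFP-positive replicate 1 (adjusted p = 0.055), GFP-positive replicate 2 (0.078) or GFP-negative replicate 1 (0.175, median 0.12), nor without dim probe sets (0.095) or with a block on replicate number (0.075). The pseudocount gave a median of 0.08, and after the span adjustment its median was 0.09 (adjusted p = 0.445). The germline list had a median of 0.41 over 12 genes (camera adjusted p = 0.0070, and adjusted p = 0.112 with an estimated correlation), and tud, a germ plasm gene, rose by 0.50 ± 0.10. The list's median was 0.27 without GFP-negative replicate 3, 0.26 without dim probe sets and 0.10 with the pseudocount, and it passed in each. Among segment polarity genes, the Wnt antagonist gene nkd rose by 0.72 ± 0.11 and the paired-type factor gsb fell by 0.60 ± 0.09. In the epidermis list, the Toll family gene 18w rose by 0.39 ± 0.07.

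Mitochondrial respiration genes had a median of -0.18 over 63 genes, 49 of them lower (camera adjusted p = 9.8e-05, and adjusted p = 0.167 with an estimated correlation), and 8 fell. Among these were the complex I subunit genes ND-B17.2 (-0.48 ± 0.06) and ND-MWFE (-0.43 ± 0.06), ATPsynCF6 (-0.38 ± 0.06) and COX5B (-0.37 ± 0.06). The median was -0.11 without GFP-positive replicate 2 and -0.11 with the pseudocount. After the adjustment for gene span, which also fits the mean level, the list's median was -0.05 (adjusted p = 0.162). The FGF/EGF/Ras list had a median of 0.25 over 15 genes (camera adjusted p = 0.0070, and adjusted p = 0.112 with an estimated correlation), and after the span adjustment 0.07 (adjusted p = 0.611). Without GFP-negative replicate 3 the median was 0.15, and with the pseudocount 0.13. Its member S (Star) rose by 0.34 ± 0.06. The heat shock and stress list had a median of 0.27 over 12 genes (camera adjusted p = 0.0048, and adjusted p = 0.112 with an estimated correlation). The members that rose were skl, a pro-apoptotic gene, by 0.72 ± 0.11 and puc, a phosphatase of the JNK pathway, by 0.48 ± 0.10. Adjusted over the list alone with the single prior variance, 0 mitochondrial, 0 FGF/EGF/Ras and 2 stress genes passed. With the level-dependent one, 18 mitochondrial genes were lower and 1 higher, and 4 FGF/EGF/Ras and 5 stress genes were higher.

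Asymmetric division genes had a median of 0.02, Wnt genes 0.14, BMP genes 0.07, Notch genes 0.00045, Hedgehog genes -0.0083, ribosomal protein genes -0.02, glycolysis genes 0.07 and yolk or fat body products -0.42, the last over 5 genes and -0.04 without GFP-positive replicate 1, and none of these lists passed. Without 1 array the Wnt median ranged from 0.086 to 0.14 and the ribosomal protein median from -0.038 to -0.0045. For the Hedgehog list the direction of the test was opposite to the median. The kinase gene par-1 rose by 0.56 ± 0.12 and numb by 0.35 ± 0.07 within the asymmetric division list. In the Notch list, the metalloprotease gene kuz rose by 0.49 ± 0.09 and Tom by 0.19 ± 0.04. Some named genes had dimmer probe sets that did not pass. The other 2 of par-1, one of them at nearly the same level, differed by -0.06 and 0.11, and the call of par-1 (adjusted p = 0.0498) was lost without each single array. Among the rest a probe set of borr differed by 0.04, of sls by 0.14 and of nkd by 0.09, and the 2 of rols by -0.09 and 0.93.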

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

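The span adjustment, the count over the same genes without it, the level-dependent refits under each setting and the hemocyte list without shared members were chosen after seeing the data. With the single prior variance, the count of 0 probe sets became 340 with the level-dependent prior variance, 20 with dim probe sets left out, 306 with the pseudocount and 515 by non-overlap with a 2-fold limit, and stayed 0 under the other settings, the replicate block included. With the level-dependent prior variance, the 340 became 655 with dim probe sets left out, 129 with the span adjustment, 36 with the 2-fold limit, and 102 to 189 without 1 array. With 1 probe set per gene and no span adjustment it was 297, and 300 over the 10803 genes with a known span, of which 106 stayed among the 129. The replicate block gave 437, of which 316 were shared with the 340. Same-numbered arrays of both groups correlated at 0.060, 0.012 and 0.024 in their deviations from the group means. Pairs of different number lay between -0.047 and 0.019, so same-numbered ones tended to be higher. GFP-positive replicate 2 did not correlate best with its own number, so pairing was not shown. It is not excluded, as the 18S control was high on replicate 3 of both groups. Settings that leave out arrays or probe sets test fewer values by construction, and otherwise the cause was not tested. Of the 340, 6 had a mean within the background.

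Of 31 lists, 13 passed. With an estimated correlation 2 did, 1 each way, and the basement membrane (median 0.65, adjusted p = 0.068) and cell division (-0.20, adjusted p = 0.104) lists did not. The cell division and pan-mesoderm lists lost the call although their estimated correlations of -0.024 and -0.156 lay below the preset 0.01. The same held for the sarcomere (-0.012), hemocyte (0.0046), neuron (-0.037), germline (-0.0047), FGF/EGF/Ras (-0.039) and stress (-0.047) lists. Correlated members therefore cannot account for those losses. With an estimated correlation camera uses the far fewer degrees of freedom of the arrays, which raises small p-values. The unadjusted camera p of the somatic muscle list thus went from 4.5e-10 to 0.0026 at an estimated correlation of -0.00041. For the basement membrane, visceral and mitochondrial lists the estimates were 0.061, 0.121 and 0.066, above the preset, so correlated members may add to their losses. The other settings of camera gave 9 to 14. The block gave 11, as the sarcomere (adjusted p = 0.066) and neuron (0.075) lists did not pass. The pseudocount brought the somatic muscle, basement membrane and DNA replication medians to 0.32, 0.38 and -0.22, which still passed. The pseudocount also brought the pan-mesoderm, visceral and stress medians to 0.19, 0.17 and 0.15, which passed. Fry asks whether a list moves as a whole, not whether it differs from other genes, so its 16 lists are no check on camera's 13. By it the epidermis (0.014), segment polarity (0.014) and Wnt (0.031) lists passed too. The Forkhead list ranged from 0.081 to 0.30 and the cardiac list from -0.086 to 0.36 without 1 array.

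Medians near 0 of lists that did not pass changed sign, and the cause was not tested. Without 1 array, the range was -0.029 to 0.051 for neuroblasts, -0.17 to 0.0070 for glia, -0.015 to 0.20 for trachea, -0.15 to 0.013 for salivary gland, -0.025 to 0.090 for asymmetric division, -0.012 to 0.18 for BMP, -0.025 to 0.036 for Notch, -0.065 to 0.068 for Hedgehog and -0.048 to 0.22 for glycolysis. With the span adjustment, medians were -0.0055 for epidermis, -0.016 for neuroblasts, -0.026 for salivary gland, -0.11 for asymmetric division, -0.00018 for BMP and 0.066 for ribosomal proteins, and jumu was at -0.051. With dim probe sets left out, salivary gland was at -0.14 and glycolysis at -0.083. With array weights, salivary gland was at -0.010, Notch at -0.0017 and Hedgehog at 0.015. The pseudocount moved salivary gland to -0.0080, and median centring moved Notch to -0.00013.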

Other observations

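Several gene families outside the fixed lists were picked because members had moved, so no test of the families themselves is given and the calls are those of single genes. The 7 Sm core proteins of the spliceosome were all lower (median -0.35), 5 of them called, with SmD3 at -0.46 ± 0.06 and SNRPG at -0.42 ± 0.07 (log2, SE, n = 3 per group). All 7 genes of replication protein A and of the clamp loader that places PCNA on DNA were lower (median -0.40), and RPA1, RPA2 and RPA3 fell. Of 5 genes named Polr2 after RNA polymerase II, all lower with a median of -0.38, 3 were called, among them Polr2E at -0.38 ± 0.06. Of 39 proteasome genes 31 were lower (median -0.18) and 3 were called, with Rpn3 at -0.42 ± 0.05. These 39 were taken by name and include dim genes whose direction means little. Of the 8 that were higher, all but Prosalpha3 and Prosbeta2R2 had both means below the background level. So had Rpn13R, Rpt3R, Prosalpha4T1, Prosbeta4R1 and Prosbeta4R2 among the lower ones.

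Integrin adhesion genes, also chosen after seeing the data, had a median of 0.42 over 13 genes, 10 of them higher. Those called were the integrin subunit genes if (0.78 ± 0.13) and mys (0.55 ± 0.07), the talin gene rhea (0.51 ± 0.06) and the dystroglycan gene Dg (0.59 ± 0.10). After the adjustment for gene span the medians were 0.25 for integrin adhesion, -0.22 for Sm proteins, -0.32 for replication protein A and clamp loader, -0.23 for the Polr2 genes and -0.06 for the proteasome.

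Of the tests below, those of RNA integrity, of the span adjustment, of other cell types, of swapped labels and of the splits with the single prior variance were chosen after the result was seen. Genes with long annotated spans were higher in GFP-positive cells. Over 5170 genes with a mean level above 4, Spearman's rho between span and log2 difference was 0.43 and Pearson's r with log2 span 0.40 (permutation p = 0.0001 for rho, the smallest that 10000 permutations can give), across genes, which are not independent replicates. Over all 10803 genes with a known span rho was 0.17 and r 0.14, and the values that follow are again for mean levels above 4. The decile medians ran from -0.18 for the shortest to 0.24 for the longest genes. Relative to the mean of the 6 arrays, which makes the groups mirror each other, each GFP-positive array showed the trend (rho from 0.20 to 0.33) and each GFP-negative array the opposite (-0.36 to -0.24), and rho lay between 0.39 and 0.46 without any 1 array. The fixed lists do not carry it, as rho was 0.43 in the 4816 such genes in no list. RNA integrity stays open: the 3' minus 5' difference of the eIF-4a control was lower by 0.13 in GFP-positive cells (-0.126, exact permutation p = 0.4) while that of actin was higher by 0.03 (exact permutation p = 0.7), too few arrays to decide.

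The span trend may account for part of the list shifts. After the span adjustment the somatic muscle, basement membrane and DNA replication lists stayed past the threshold, with medians of 0.50, 0.57 and -0.29. The highest camera adjusted p was 3.7e-07, which argues against span as their whole cause, as far as the adjustment removed the trend. The rho left on the real arrays after the adjustment was not measured. The adjustment was tested at the preset correlation, and at an estimated one the basement membrane list did not pass even before it (adjusted p = 0.068). For the mitochondrial respiration list the median moved from -0.18 to -0.05 and the adjusted p from 9.8e-05 to 0.162, so its call ended because the shift shrank. A biological difference that itself follows gene span is not separated from a technical one by this adjustment. It also took out any trend with the mean level, which was not fitted alone, so span and level are not told apart.

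Markers of neural, epidermal and tracheal cells were not depleted from the GFP-positive fraction. Over 60 such genes above background the median log2 difference was 0.09 (0.0908), the median level was 6.52 in GFP-positive and 6.44 in GFP-negative cells, and 0 genes were lower by 1 or more. A candidate explanation is that cells of other types made up much of the GFP-positive fraction, which the sort on GFP was meant to remove. Labels swapped between the groups are not excluded: the somatic muscle list (median 0.62) was higher in the arrays labelled GFP-positive at both correlations, and all 10 visceral mesoderm genes were higher (median 0.41), but the visceral and pan-mesoderm (median 0.31) lists did not pass at an estimated one (adjusted p = 0.112 and 0.104), and the cardiac list, nearest to the reporter, had a median of 0.06 with pnr at -0.29. Expression of these markers in the labelled cells themselves stays open and was not tested.

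The 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. With the single prior variance the real split gave 0 calls and the highest of the others 2, so 10 of 10 splits gave as many. With the level-dependent prior variance the real split gave 340 and the highest other 0, so 1 of 10 gave as many. For gene lists the real split gave 13 and the highest other 2, again 1 of 10.

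On individual arrays, the 18S rRNA control was at 7.57 on GFP-positive and 7.82 on GFP-negative replicate 3, against 5.05 to 6.10 on the other 4 arrays. The mean of the hybridization controls was 8.06 on GFP-negative replicate 1 and between 8.88 and 9.26 on the others.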
